A study of Homo sapiens with 6 samples.

How the data were processed

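RNA from 6 samples of cells labelled H358 was measured by sequencing. H358 is an established human cell line of non-small cell lung cancer, and the 6 libraries form 2 groups of 3. In the shPGAM5 group the cells carried a short hairpin RNA (shRNA) against PGAM5, a phosphatase of the mitochondrial membrane. In the shCON group they carried a scrambled hairpin that serves as the negative control. Per the labels' protocols, hairpin plasmids were delivered with a lipid reagent and cells were harvested 36 h later, whereas the series' own design text speaks of a stable knockdown. The data do not settle which of the 2 accounts holds. The number of hairpins against PGAM5 and their sequences are not given. Effects of a hairpin on other genes, or other differences between the cells of the 2 groups, therefore cannot be told apart from an effect of lower PGAM5. Libraries were made with a NEBNext Ultra RNA kit, per the labels, and no strand setting is stated, so reads of genes that overlap on opposite strands cannot be told apart.

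The deposited table holds 1 row per gene, 34358 in all, with a count and an FPKM value per library. Per the submitters' processing notes, HISAT2, StringTie and SAMtools were used with genome build hg38; no version, role or order is recorded. The deposited counts are whole numbers per gene that the authors did not normalize, per the file headers and the values. The deposited FPKM values are the authors' counts scaled to gene length and to the mapped fragments of the library, per the file headers. The annotation release is not stated. Of 32632 identifiers that are also in GENCODE release 29, 99.9% overlapped the position given there on the same build.

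Total counts per library were 75984524, 76317295 and 73937573 in shCON and 76386743, 79479013 and 90836880 in shPGAM5. In each library more genes were listed at 4 counts than at 3 or 5, and more at 8 than at 7 or 9, so that 1 fragment appears to have been counted about 4 times. The totals would then stand for 18484393 to 22709220 fragments, and the precision of a low count is lower than its size implies. Dividing counts by 4 was therefore tried as an alternative. Divided by 4, the counts of libraries of 1 group still differed by more than sampling noise: the median chi-square per gene was 0.722 to 2.30, against 0.455 with sampling noise alone. The 6 libraries were counted as separate samples. Nothing in the labels says that they came from separate cultures or transfections, so the p-values measure the spread between these samples, which may be technical.

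The main test was chosen before the data were examined. It was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with filterByExpr (minimum count 10, minimum total 15), TMM normalization and group as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. The standard error of a log2 fold change was approximated as its size divided by the square root of the F statistic. The written plan assumed FPKM alone and named edgeR for the case that counts were present. limma 3.58.1 on log2(FPKM + 1), for genes of at least 1 FPKM in at least 3 libraries, became an alternative. Values of single measures were compared with an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p below 0.1. Replicate numbers were not taken as pairs in the main fit.

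Groups of genes were compared with 31 lists fixed before the data were examined, with 791 symbols, of which 768 matched a gene of the table. Each list was tested with camera in limma, a two-sided test of whether the members move against all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 31 lists. The same test with a correlation estimated from the data, and fry, were run beside it. Fry asks only whether members move, on balance, one way, and called 25 of 31 lists. Terms of the Gene Ontology (GO) and of KEGG were taken from the deposited table, in which 15547 genes carried a GO term and 6758 a KEGG term; part of the terms had been removed from the table. Terms of 10 to 500 tested genes were compared with a one-sided Fisher's exact test, rises and falls apart. The background was all tested genes with at least 1 term of that kind, and adjustment was within kind and direction.

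Genes named in the text follow a rule fixed beforehand. It takes PGAM5, and the 12 largest rises and 12 largest falls among changed genes with mean FPKM of at least 2 and groups that do not overlap. It adds up to 4 changed members per list with the largest change, 10 genes of pyruvate and lactate handling, and KEAP1, FUNDC1, DNM1L and BCL2L1 as known partners of PGAM5. Clone names, pseudogenes and repeated symbols were left out. Members named outside the rule, because few members fell or did not pass, or as examples of a term, were chosen after their values were seen.

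The test was checked on simulated data with the means and totals of these libraries, 19935 genes, 100 genes changed at each of 2 fold sizes and a list of 30 more raised by 0.5 on the log2 scale. For shPGAM5 against shCON, edgeR recovered 56% of genes changed by 1.5-fold and 71% of genes changed by 2-fold, with false calls at 4.64% of calls. limma on FPKM recovered 36% and 53%, with 2% false calls. DESeq2 recovered 59% and 72%, with 15.9% false calls. In the real comparison 43.9% of genes were called, far more than the simulation changed. Simulated genes also took their spread from the trend over expression level alone. These rates therefore do not carry over to the real comparison. Alternatives were limma on FPKM with pseudocounts of 0.1, 1 and 5, TMM-like and quantile scaling, DESeq2 1.42.0, no filter on low counts, a minimum mean FPKM of 5, a replicate block, a robust fit, a minimum fold, and leaving out each library. Size factors of DESeq2 in edgeR, library totals alone, counts divided by 4 and a term background of mean FPKM of at least 5 were chosen after seeing the data. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.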

Results

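Gene expression was measured in cells labelled H358, a human line of non-small cell lung cancer, after knockdown of PGAM5 and with a scrambled control hairpin. PGAM5 is a serine/threonine phosphatase of the mitochondrial membrane with known roles in mitophagy and cell death. There were 3 libraries labelled shPGAM5 and 3 labelled shCON, with total counts of 73937573 to 90836880, or about 18484393 to 22709220 fragments at the apparent 4 counts per fragment. The title of the series places the work in the production of lactate through pyruvate metabolism, and the only comparison of the design asks how expression differs between knockdown and control. Values are mean FPKM ± SD over n = 3 libraries per group, log2 fold changes are shPGAM5 over shCON with their SE, and adjusted p-values of genes are from edgeR with Benjamini-Hochberg adjustment.

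The targeted gene was lower in each shPGAM5 library. PGAM5 (ENSG00000247077, hg38 chromosome 12, 132710819 to 132722734, plus strand) measured 26.0, 26.4 and 23.7 FPKM in the shCON libraries and 3.19, 3.48 and 2.52 FPKM in the shPGAM5 libraries. The group means were 25.4 ± 1.5 and 3.06 ± 0.49 FPKM. By the edgeR fit on counts, 12.5% of the control level was left (log2 fold change -3.00, SE 0.11, edgeR adjusted p = 8.8e-08). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Among known partners of PGAM5, KEAP1, the adaptor that targets NRF2 for degradation, fell from 32.9 ± 0.92 to 25.9 ± 1.3 FPKM. FUNDC1, a mitophagy receptor, fell by 0.22 on the log2 scale and DNM1L, the GTPase of mitochondrial fission, rose by 0.13 (edgeR adjusted p = 0.038 and 0.036). Both calls were lost in several alternatives, among them the fit without a filter on low counts. BCL2L1, an inhibitor of apoptosis, had a log2 fold change of -0.07 and did not pass (adjusted p = 0.34).

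Transcripts of the enzymes that make lactate were higher in shPGAM5 than in shCON. LDHA, the lactate dehydrogenase subunit that favours the reduction of pyruvate to lactate, rose from 155 ± 6.5 to 338 ± 12 FPKM (log2 fold change 1.17, SE 0.05, edgeR adjusted p = 1.8e-07). PKM, which encodes pyruvate kinase, rose from 366 ± 3.6 to 501 ± 14 FPKM, and LDHB rose from 226 ± 3.7 to 269 ± 3.1 FPKM. PDK1, a kinase that inhibits the pyruvate dehydrogenase complex, rose from 0.682 ± 0.027 to 2.35 ± 0.039 FPKM (log2 fold change 1.83). PC, the pyruvate carboxylase, rose from 20.1 ± 0.67 to 29.2 ± 2.3 FPKM, although its exons overlap LRFN4 and some of its reads may belong there. The call for LDHB was lost after quantile scaling of FPKM, where its log2 fold change was 0.03.

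Pyruvate dehydrogenase and the carriers of pyruvate and lactate differed by 0.19 or less on the log2 scale. PDHA1, a subunit of pyruvate dehydrogenase, measured 25.7 ± 0.67 and 26.4 ± 0.74 FPKM in shCON and shPGAM5 and did not pass (edgeR adjusted p = 0.10). The mitochondrial pyruvate carrier subunit MPC1 measured 11 ± 0.67 and 10.8 ± 0.80 FPKM and did not pass, and MPC2 fell by 0.19 on the log2 scale. MPC2 shares exon sequence with DCAF6, and its call was lost without shCON replicate 2 (log2 fold change -0.15). The lactate transporters SLC16A1 and SLC16A3 rose by 0.17 and 0.12, and the call for SLC16A3 was lost in 11 of its alternatives, the fit on FPKM included.

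**Figure D1:**
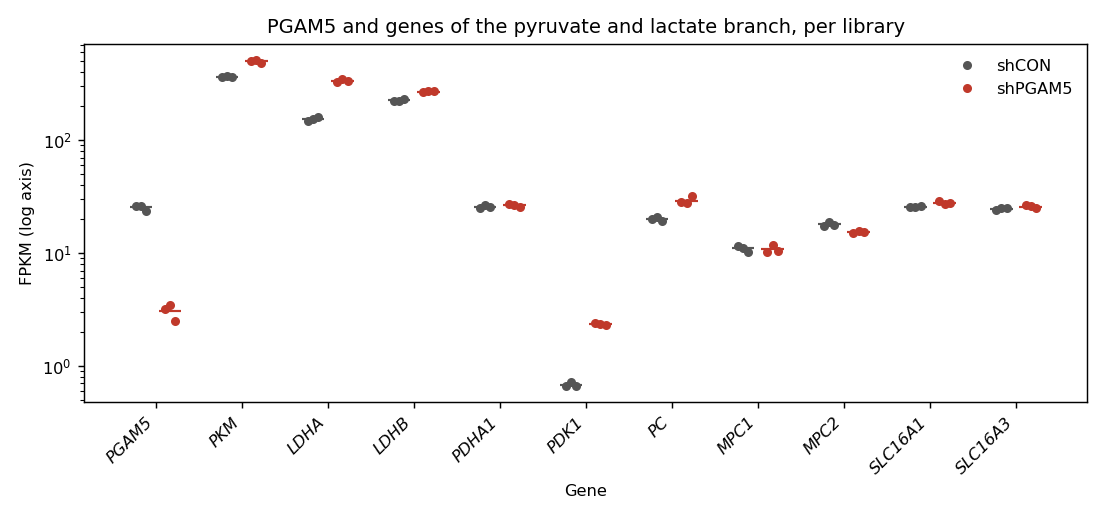
FPKM per library, on a log axis, of PGAM5 and 10 genes of pyruvate and lactate handling. Each point is 1 library, grey for shCON and red for shPGAM5, and each line is the mean of 3 libraries; PGAM5 lies at 23.7 to 26.4 FPKM in shCON and 2.52 to 3.48 in shPGAM5, and LDHA has means of 155 and 338.

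Most glycolytic genes rose together. Of 21 members of the glycolysis list, 17 rose, 2 fell and 2 did not pass, and the counts were the same adjusted over the list alone. The median log2 fold change was 0.49 (camera adjusted p = 2.6e-13; adjusted p = 0.27 with an estimated correlation). SLC2A3, a glucose transporter, rose from 2.11 ± 0.092 to 8.25 ± 1.2 FPKM, ALDOC from 12.4 ± 1.1 to 24.8 ± 3.0 FPKM, and PGK1 from 92.1 ± 2.4 to 164 ± 7.7 FPKM. The members that fell were PFKFB3 (log2 fold change -0.42), which makes an activator of phosphofructokinase, and SLC2A1 (-0.20), a glucose transporter.

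In the pyruvate metabolism list, 18 of 33 members rose, 5 fell and 10 did not pass (19 rose and 5 fell adjusted over the list alone). The median log2 fold change was 0.18, with a camera adjusted p of 3.7e-04 (adjusted p = 0.38 with an estimated correlation). Besides LDHA, PKM and PC, the rises included ACSS1 (log2 fold change 0.88) and ACAT2 (0.65), whose exons overlap the abundant TCP1. ACYP2 fell from 0.507 ± 0.020 to 0.218 ± 0.033 FPKM, and ME3, ACACB, HAGH and ALDH2 also fell. In the list of pyruvate and lactate transport and control of pyruvate dehydrogenase, 7 of 13 members rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.025 (adjusted p = 0.49 with an estimated correlation). Members of opposite action rose in it: PDK1 and PDK3 inhibit pyruvate dehydrogenase and PDP2 activates it. This call was lost in all 5 fits on FPKM and at a minimum mean FPKM of 5.

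Hypoxia-type targets and NRF2 targets were higher in shPGAM5. Of 23 hypoxia targets, 14 rose, 5 fell and 4 did not pass (14 and 6 adjusted over the list alone; median 0.55, camera adjusted p = 3.9e-06; adjusted p = 0.38 with an estimated correlation). CA9, a carbonic anhydrase of the cell surface, rose from 1.07 ± 0.42 to 17.9 ± 4.3 FPKM. EGLN3, an oxygen-sensing hydroxylase, rose from 0.106 ± 0.0067 to 0.453 ± 0.074 FPKM. ANGPTL4 fell from 55.5 ± 5.8 to 17.9 ± 2.5 FPKM, and VEGFA, ADM, SLC2A1 and BHLHE40 also fell. Of 24 NRF2 targets, 14 rose and 7 fell, counts that were the same adjusted over the list alone (median 0.40, camera adjusted p = 2.4e-05; adjusted p = 0.38 with an estimated correlation). AKR1B10, an aldo-keto reductase, rose from 14.5 ± 1.4 to 52.8 ± 6.5 FPKM, and ABCC2, an export pump, rose from 0.533 ± 0.071 to 2.25 ± 0.19 FPKM. The paralogs AKR1C2 and AKR1C3 rose by 0.85 and 0.83 and may share reads. The NRF2 target NQO1 measured 216 ± 8.2 and 214 ± 5.8 FPKM in shCON and shPGAM5 and did not pass (edgeR adjusted p = 0.58). NFE2L2, which encodes NRF2, fell from 7.95 ± 0.23 to 5.94 ± 0.064 FPKM. Both were looked up after other values had been seen. The list's call was lost with quantile scaling of FPKM (adjusted p = 0.21).

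Interferon-stimulated genes were lower in shPGAM5. All 33 tested members of the interferon list fell, and 33 did so adjusted over the list alone (median log2 fold change -1.86, camera adjusted p = 2.0e-28; adjusted p = 0.38 with an estimated correlation). IFI27 fell from 5.14 ± 1.8 to 0.265 ± 0.037 FPKM, CXCL10 from 1.10 ± 0.31 to 0.0138 ± 0.024 FPKM, and RSAD2 from 0.957 ± 0.33 to 0.0131 ± 0.016 FPKM. XAF1 fell from 0.732 ± 0.19 to 0.0134 ± 0.012 FPKM. The list was of low to moderate level, with a median of 6.80 FPKM in shCON and 1.72 in shPGAM5.

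Cytokine genes moved both ways. In the inflammatory NF-kB list 13 of 31 members rose and 12 fell (13 and 13 adjusted over the list alone), with a median of -0.11 and a camera adjusted p of 0.0010 (adjusted p = 0.38 with an estimated correlation). IL1B fell from 249 ± 5.5 to 17.8 ± 0.20 FPKM, IL1A from 35.6 ± 2.3 to 4.81 ± 0.37 FPKM, and CCL2 from 254 ± 6.8 to 89.2 ± 9.8 FPKM. CSF3, a growth factor of granulocytes, rose from 0.194 ± 0.073 to 0.864 ± 0.087 FPKM. The list's call was lost in all 5 fits on FPKM and with no filter on low counts.

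Mitotic and ribosomal genes rose. Of 32 G2/M and mitosis genes 31 rose, also adjusted over the list alone, and AURKA (0.04) did not pass (median 0.70, camera adjusted p = 2.0e-27; adjusted p = 0.38 with an estimated correlation). CDC25B, a phosphatase that starts mitosis, rose from 24.0 ± 0.35 to 53 ± 1.8 FPKM, and KIF20A, a mitotic kinesin, from 15.3 ± 0.47 to 32.2 ± 1.7 FPKM. Of 75 cytosolic ribosomal protein genes 74 rose, also adjusted over the list alone, and RPL23A (0.05) did not pass (median 0.43, camera adjusted p = 2.8e-23; adjusted p = 0.42 with an estimated correlation). RPS2 rose from 483 ± 13 to 830 ± 49 FPKM and RPL12 from 117 ± 4.2 to 209 ± 14 FPKM. Their share of all counts was 3.77% ± 0.059 in shCON and 5.05% ± 0.30 in shPGAM5 (exact permutation p = 0.1).

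Lipid synthesis genes were higher. Of 17 fatty acid synthesis genes 11 rose and 3 fell, also adjusted over the list alone (median 0.40, camera adjusted p = 3.7e-04; adjusted p = 0.38 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose from 46.8 ± 0.98 to 108 ± 5.8 FPKM and FASN, the fatty acid synthase, from 34.4 ± 0.64 to 49.8 ± 3.2 FPKM. ACACB, ELOVL1 and ACSL1 fell. Of 24 cholesterol synthesis genes 15 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.24, camera adjusted p = 0.0028; adjusted p = 0.49 with an estimated correlation). INSIG1 rose by 0.55, whereas HMGCS1 and TM7SF2 fell.

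The 11 lists described so far and the fibroblast markers made up the 12 of 31 lists that passed, 10 upward and 2 downward. With an estimated correlation 0 lists passed, 2 had an unadjusted camera p under 0.05, and fry called 25. The remaining lists did not pass in edgeR with the preset correlation. Those of the citric acid cycle, oxidative phosphorylation, mitochondrial mRNAs, S phase, histones and WNT targets did in 1 or more alternatives. Of 21 genes of the citric acid cycle 11 rose and 3 fell (11 and 3 adjusted over the list alone), with IDH2 and MDH2 up by 0.57 and 0.38. Of 73 nuclear genes of oxidative phosphorylation 25 rose and 3 fell (25 and 3 adjusted over the list alone), led by ATP5MC2 (0.90). Of 13 mRNAs of mitochondrial DNA 6 rose and 1, MT-ND2, fell (7 and 1 adjusted over the list alone). The counts of mitochondrial transcripts were 4.16% ± 0.15 of the total in shCON and 4.65% ± 0.28 in shPGAM5 (exact permutation p = 0.1). Of 24 genes of mitophagy and mitochondrial dynamics 9 rose and 12 fell, also adjusted over the list alone. PINK1, the kinase that marks damaged mitochondria, fell from 29.8 ± 0.39 to 11.4 ± 1.0 FPKM, with an antisense gene over part of its exons, and the receptor BNIP3 rose from 22.0 ± 0.77 to 48.2 ± 1.1 FPKM. GABARAPL1 and SQSTM1 fell by 1.04 and 0.75 on the log2 scale. Of 12 mitochondrial biogenesis genes 3 rose, also adjusted over the list alone.

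Growth and stress lists were mixed. Of 34 S phase genes 14 rose and 3 fell (18 and 4 adjusted over the list alone), and of 15 replication-dependent histone genes tested 0 rose and 6 fell, also adjusted over the list alone, with H2AC6 at 11.1 ± 1.1 and 3.52 ± 0.30 FPKM. The histone list had a median of 0.02 and a mean of -0.35, and camera put it downward. It did not pass in the main fit, but passed downward in all 5 fits on FPKM and with counts divided by 4. Of the 35 histone genes found in the data, 28 had a mean under 1 FPKM. The fits on FPKM, limited to genes of at least 1 FPKM in at least 3 libraries, therefore rest on few members. Of 15 WNT targets 6 rose and 1 fell (the same over the list alone), with DKK1 up from 7.89 ± 1.4 to 33.6 ± 3.4 FPKM. Of 28 ATF4 targets 10 rose and 8 fell (12 and 10 adjusted over the list alone), with DDIT4 up from 36.1 ± 5.2 to 133 ± 25 FPKM and STC2 down from 74.9 ± 3.1 to 22.5 ± 2.5 FPKM. Its median was -0.0022, its mean 0.04, and camera put it upward. Of 21 p53 targets 9 rose and 6 fell (9 and 7 adjusted over the list alone), with CDKN1A, the cell cycle inhibitor, down from 39.3 ± 0.92 to 8.32 ± 0.22 FPKM. The median was 0.02, the mean -0.03 and the camera direction downward. Of 31 cell death genes 8 rose and 12 fell, also adjusted over the list alone, with BIK, a pro-apoptotic gene, down from 7.52 ± 0.50 to 1.48 ± 0.53 FPKM. Of 22 MAPK output genes 3 rose and 10 fell (4 and 11 adjusted over the list alone), with DUSP4 down by 1.09 and MYC up by 0.68. Of 23 heat shock and immediate early genes 6 rose and 12 fell (6 and 13 adjusted over the list alone), with HSPB1 up from 67.7 ± 2.0 to 139 ± 7.9 FPKM. Of 21 fatty acid oxidation genes 5 rose and 7 fell (6 and 7 adjusted over the list alone), with CPT1A, the entry step, down from 24.0 ± 0.58 to 11.3 ± 0.35 FPKM.

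Markers of cell identity were compared in both groups. Of 16 tested epithelial genes 9 rose and 3 fell (10 and 4 adjusted over the list alone), and ELF3 rose from 0.175 ± 0.031 to 1.41 ± 0.35 FPKM. Of 23 mesenchymal genes 10 rose and 8 fell (10 and 10 adjusted over the list alone). LOX, which crosslinks collagen, rose from 9 ± 0.38 to 43.0 ± 4.3 FPKM. The median was -0.08, the mean 0.09 and the camera direction upward. Of 8 tested lung lineage genes 3 rose and 3 fell, also adjusted over the list alone. Of 11 fibroblast markers 7 rose and 1, PDGFRB, fell (7 and 2 adjusted over the list alone; median 1.10, camera adjusted p = 2.4e-05; adjusted p = 0.41 with an estimated correlation). COL1A1 rose from 129 ± 3.7 to 292 ± 13 FPKM and COL3A1 from 5.49 ± 1.0 to 37.4 ± 6.0 FPKM, while COL1A2 measured 0.00921 ± 0.0083 and 0.0900 ± 0.030 FPKM. This call was lost with TMM-like and quantile scaling of FPKM, where the median was 0.25 and 0.13 (adjusted p = 0.064 and 0.13). Of 6 leukocyte markers 3 rose and 1 fell, and of 6 endothelial markers 1, PECAM1, fell; counts were the same adjusted over each list alone.

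Across all genes, 8754 of 19935 tested changed in edgeR, or 43.9%, with 4226 higher and 4528 lower in shPGAM5. Lower PGAM5 and other effects of the hairpins cannot be told apart as the source of these changes. The changes were mostly small: 5321 of them, or 60.8%, were under 1.5-fold, and 1783 reached 2-fold, 909 upward and 874 downward. The groups did not overlap at 55.6% of tested genes, against 10% by chance. Libraries of 1 group correlated at 0.994 to 0.997 over genes and libraries of different groups at 0.976 to 0.978, and the first principal component, with 79.1% of the variance, separated the groups. Pearson correlations here are across genes, which are not independent replicates.

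The largest rises were in SERPINB3 and SERPINB4, paralogous serpins that inhibit proteases and may share reads. SERPINB3 rose from 0.248 ± 0.13 to 51.7 ± 16 FPKM (log2 fold change 7.73, SE 0.33, edgeR adjusted p = 2.6e-07) and SERPINB4 from 0.400 ± 0.16 to 24.7 ± 6.3 FPKM. NNMT, a nicotinamide methyltransferase, rose from 8.39 ± 0.42 to 59.8 ± 4.2 FPKM, and PTX3, a secreted pattern recognition protein, from 5.76 ± 0.36 to 33.9 ± 2.8 FPKM. SOCS1, an inhibitor of cytokine signalling, rose from 0.852 ± 0.077 to 5.38 ± 0.64 FPKM. CA9, CES1, RASL11A, LAMC3, COL3A1, EVI2B and LOX completed the 12, with log2 fold changes of 2.30 to 4.11.

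The largest falls included PIP and 3 cystatin genes. PIP, a secreted protein, measured 16.5 ± 3.0 FPKM in shCON and was listed at 0 in each shPGAM5 library, at least 210-fold lower against a floor of 12 counts, or 3 fragments, over the group. The cystatin genes CST1, CST2 and CST4, paralogs that may share reads, fell from 66.4 ± 3.9 to 0.667 ± 0.13, from 11.1 ± 1.1 to 0.792 ± 0.23 and from 212 ± 18 to 2.98 ± 0.48 FPKM. ALOX5AP, which activates 5-lipoxygenase, fell from 19.3 ± 1.5 to 0.504 ± 0.076 FPKM. SLC16A6, a monocarboxylate transporter family member, fell from 40.0 ± 2.2 to 3.24 ± 0.37 FPKM (log2 fold change -3.58, SE 0.08, edgeR adjusted p = 8.1e-09). ASB2, IFI27, BEX1, LINC00996, IL1B and SCG5 made up the rest, with log2 fold changes of -6.18 to -3.65. Pseudocounts on FPKM shrank most of these sizes: SERPINB3 was at 5.37 in the fit on log2(FPKM + 1).

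**Figure D2:**
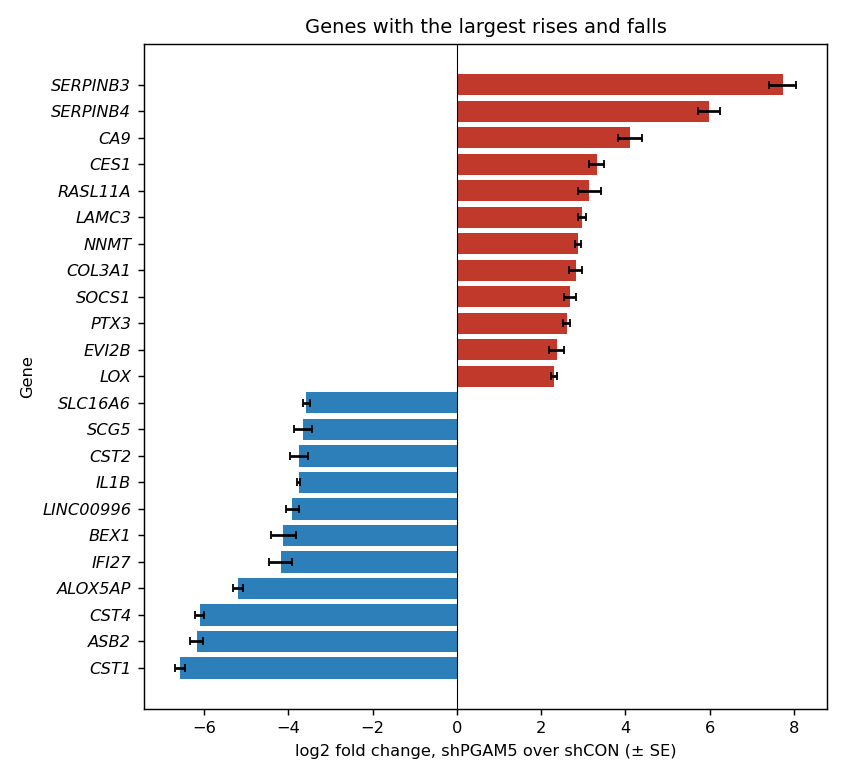
Log2 fold change, shPGAM5 over shCON, of 23 of the 24 genes with the largest changes. Bars start at 0 and are red for rises and blue for falls. Whiskers are the SE approximated from the F statistic of the edgeR test, with 3 libraries per group. PIP is left out because it was listed at 0 in shPGAM5, and values run from -6.57 for CST1 to 7.73 for SERPINB3.

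Annotated terms were enriched among both rises and falls. Among genes that fell, 78 of 2268 GO terms and 32 of 324 KEGG pathways were enriched (Fisher's exact test, adjusted). The KEGG proteasome set had 32 of 43 genes down, with 12.4 by chance (adjusted p = 2.3e-07), and the GO proteasome accessory complex 16 of 16. The GO term autophagy had 75 of 130 genes down, with 36.2 by chance (adjusted p = 6.1e-10), and lysosomal membrane 123 of 259. Defense response to virus had 53 of 108 genes down, with 30.1 by chance (adjusted p = 2.5e-04). Among genes that rose, 61 GO terms and 8 KEGG pathways were enriched. Cytosolic ribosome had 69 of 70 genes up, with 16.9 by chance (adjusted p = 1.5e-38), and collagen-containing extracellular matrix 79 of 184, with 44.3 by chance (adjusted p = 2.2e-06). The KEGG glycolysis and gluconeogenesis set had 24 of 46 genes up, with 12.8 by chance. Among genes with a mean FPKM of at least 5, 112 terms passed in place of 179, and neither this KEGG set nor the virus term was among them. The GO term glycolytic process was, with 13 of 18 genes up (adjusted p = 0.0071). Fisher's test takes genes as independent, so its p-values are too small for genes that move together. The estimated inter-gene correlation was 0.76 in the ribosomal protein list and 0.80 in the interferon list. Terms of ribosomes, glycolysis and virus defense come from the same 6 libraries and can hold the same genes as the lists. They are no separate support for the lists.

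**Figure D3:**
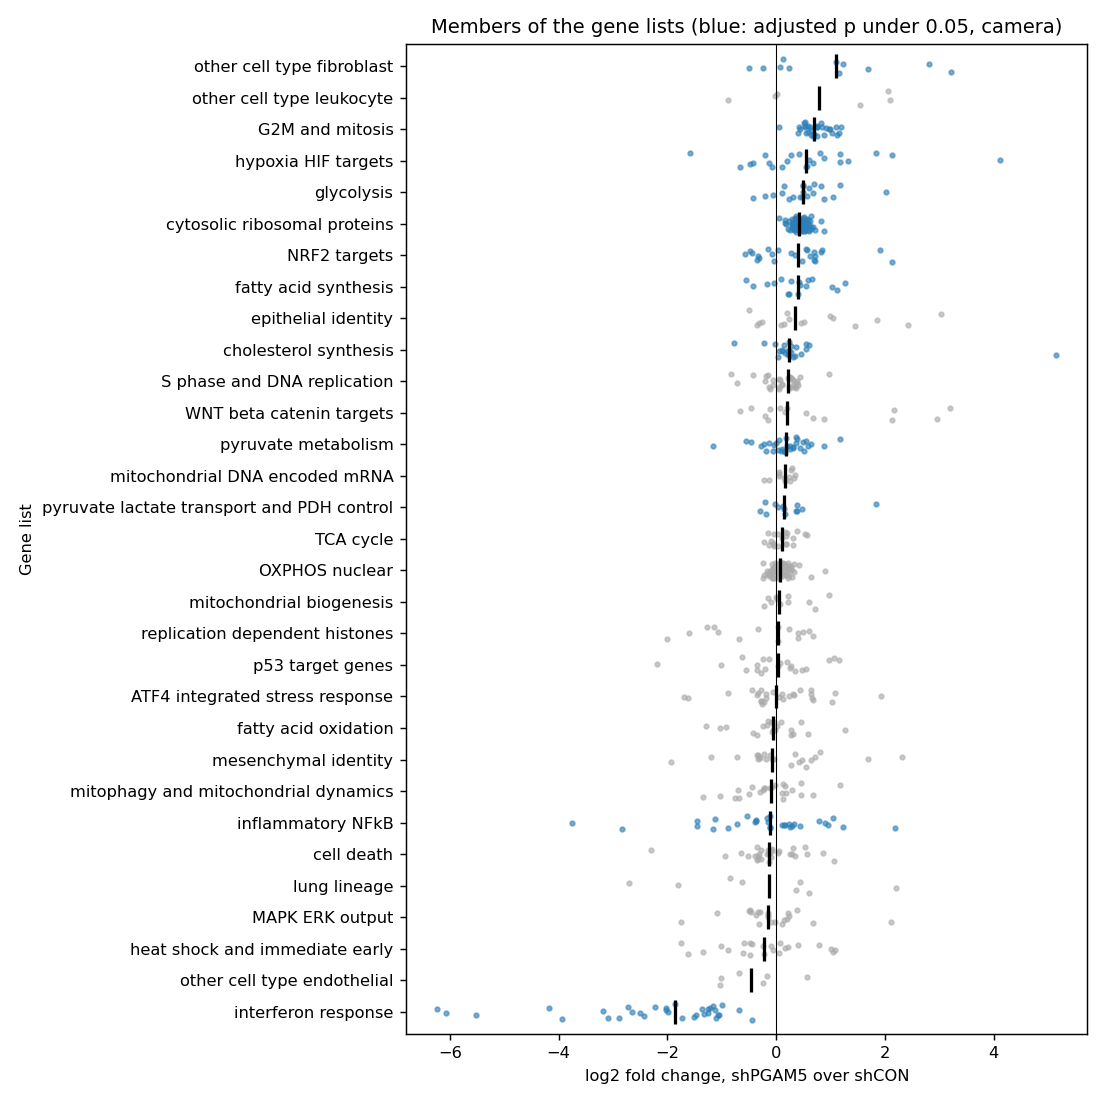
Log2 fold change, shPGAM5 over shCON, of the tested members of each of the 31 lists. Each point is a gene, black lines are list medians, and blue marks the 12 lists with a camera adjusted p under 0.05; the interferon list has a median of -1.86 and the G2/M list of 0.70.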

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

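Size factors of DESeq2 in edgeR, library totals alone, counts divided by 4 and the term background of mean FPKM of at least 5 were chosen after seeing the data. Of 2630 values of named genes under the alternatives, 2551 kept direction and side of the threshold, 69 were no longer past it, 3 newly passed and 7 changed sign; of 572 values of lists these numbers were 508, 25, 16 and 23. DESeq2 called 9001 genes and limma on FPKM 7511 of 12394, of which 6676 were also called by edgeR, in the same direction. At a minimum mean FPKM of 5, where fewer genes were tested, 4672 changed (2303 higher, 2369 lower), and with a minimum log2 fold change of 1, 1783 (909 and 874). The share of calls that were higher was 48.3%, and 39.7% to 50.5% in the other fits. With an estimated correlation 0 lists passed, with the glycolysis list at 0.49 (adjusted p = 0.27) and pyruvate metabolism at 0.18 (adjusted p = 0.38). The term background of mean FPKM of at least 5 gave 112 terms in place of 179. Without 1 library, changed genes were 7310 to 8511 (3509 to 4119 higher, 3743 to 4486 lower), lists past the threshold 12 to 14, PGAM5 -3.11 to -2.88, glycolysis 0.49 to 0.52 and pyruvate metabolism 0.15 to 0.23.

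Apart from MT-ND6 (edgeR adjusted p = 0.020), results that changed direction had not passed the test, and the cause was not tested. The histone list newly passed, downward, in all 5 fits on FPKM, with medians of -1.12 to -0.27 (adjusted p = 0.015 to 0.039), and with counts divided by 4 (-0.98, adjusted p = 0.042). With no filter on low counts the lists of the citric acid cycle (0.12), oxidative phosphorylation (0.083), mitochondrial mRNAs (0.17) and S phase (0.23) newly passed upward (adjusted p = 0.0067 to 0.036). Oxidative phosphorylation also did so with TMM-like scaling (0.087, adjusted p = 0.024) and without shPGAM5 replicate 1 (0.10, adjusted p = 0.047). Without shPGAM5 replicate 3, mitochondrial mRNAs (0.24, adjusted p = 0.0077) and S phase (0.26, adjusted p = 0.0049) did so. PDHA1 newly passed upward with TMM-like and quantile scaling and at a minimum mean FPKM of 5 (0.10, 0.093 and 0.10, adjusted p = 0.041 to 0.046). The fibroblast list, at 1.10 in edgeR, had medians of 0.13 to 0.25 in the 5 fits on FPKM (adjusted p = 0.042 to 0.13) and 0.25 at a minimum mean FPKM of 5. For lists the direction is that of camera and the value the median, and the signs can differ. The lung lineage list was at 0.30 on FPKM, 0.32 and 0.13 with pseudocounts of 0.1 and 5, 0.36 and 0.38 with TMM-like and quantile scaling, and 0.61 with no filter on low counts. The leukocyte list was at -0.061, -0.064, -0.051, -0.0014 and 0.0026 in the same 5 fits on FPKM, 0.0016 at a minimum mean FPKM of 5, 0.010 for counts divided by 4, and -0.039 to 0.75 without 1 library. MPC1 was at -0.023, -0.025 and -0.017 on FPKM with pseudocounts of 1, 0.1 and 5, -0.022 with library totals alone, and -0.040 to 0.068 without 1 library. Quantile scaling gave -0.14 for mitochondrial mRNAs, -0.037 for the mesenchymal list and -0.083 for MT-ND6. At a minimum mean FPKM of 5 the epithelial list was at 0.17, with the camera direction downward, and the mesenchymal list at -0.079; the latter was at -0.13 to -0.037 without 1 library.

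With the replicate number as a block 8320 genes changed, 8113 of them in common with 8754. Samples of equal number deviated together at r of 0.11, 0.03 and -0.02, and samples of unequal number at -0.12 to 0.09. These values gave no clear sign that the numbers pair the samples, but cannot exclude shared batches. The block ended the calls for SLC16A3, DNM1L, FUNDC1, ESRP2 and LYZ among named genes, and the WNT list newly passed (0.20, adjusted p = 0.025), as it did without shCON replicate 3 (0.22, adjusted p = 0.049). Depth limits genes near 0 FPKM such as CXCL10 and RSAD2 in shPGAM5, whose fold changes rest on few fragments.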

Other observations

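Tests that weigh GC content and transcript length, hypoxia-type targets, hairpin controls and splits of the samples were chosen after the result was seen; those on pseudogenes and on both lists of transcription targets were written before their values were seen. Their set tests are camera with the preset correlation, under which the lists' calls were made; with an estimated correlation 0 of 31 lists passed.

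Proteasome terms were enriched among the falls. Of 7 subunits looked up after other values had been seen, 6 of the regulatory particle were lower in shPGAM5: PSMD2 fell from 139 ± 3.1 to 92.1 ± 7.2 FPKM (SD, n = 3), PSMC4 from 97.1 ± 0.60 to 64.8 ± 5.7 FPKM and PSMD12 from 32.9 ± 0.34 to 20.6 ± 2.6 FPKM, while PSMD11, PSMC2 and PSMD1 fell by 0.45, 0.36 and 0.33 on the log2 scale. The core subunit PSMA3, at 42.9 ± 0.60 and 40.2 ± 2.6 FPKM, did not pass (edgeR adjusted p = 0.48). As the only core subunit looked up, PSMA3 cannot stand for the core. The GO term proteasome complex, which also holds core subunits, had 37 of 52 genes down, and the proteasome accessory complex 16 of 16. HIF1A and EPAS1, which encode oxygen-regulated transcription factors, rose by 0.69 and 1.18 on the log2 scale.

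Markers of cell type were looked up in both groups. In shCON and shPGAM5, CDH1 measured 0.0571 ± 0.013 and 0.116 ± 0.045 FPKM, EPCAM 1.13 ± 0.076 and 1.56 ± 0.35 FPKM, VIM 424 ± 6.8 and 643 ± 79 FPKM, and CDH2 99.6 ± 0.56 and 76.8 ± 3.8 FPKM (SD, n = 3). The lung markers NKX2-1 and SFTPB had 0 counts in shCON and 8 and 1 counts in shPGAM5. The epithelial keratins KRT7, KRT8, KRT18 and KRT19 were abundant, at 136 ± 3.1, 36.5 ± 1.6, 32.2 ± 0.93 and 47.2 ± 0.70 FPKM in shCON and 93.2 ± 3.0, 48.6 ± 2.3, 34.7 ± 3.2 and 53.8 ± 4.4 FPKM in shPGAM5. No reference profile of H358 was at hand, so the name of the line is that of the labels, and the low CDH1 and EPCAM leave its identity open. These values were looked up after others had been seen, and no explanation was tested.

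The interferon list fell at 33 of 33 tested members, with a median log2 fold change of -1.86. A loess trend of the fold change on GC content and transcript length explained 0.11% of the variance, so that removing it weighed little. In its place, genes outside the list were matched on both, read from the longest annotated transcript, 20 per member and 660 in all. Their median was 0.0077, which argues against such a bias as far as that transcript is the one counted. A control hairpin that raised these genes may also account for the difference, since their median was 6.80 FPKM in shCON and 1.72 in shPGAM5; without a library free of hairpins this cannot be told apart from an effect of the knockdown. The knockdown itself stays open, untested beyond the comparison.

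The glycolysis list rose at 17 of 21 members, with a median of 0.49. The 420 genes matched in the same way had a median of -0.017, which argues against a bias of GC content or length, with the same limit. A hypoxia-type response is a possible explanation that stays open. The 19 hypoxia targets outside the glycolysis and pyruvate lists had a median of 0.55, and 12 rose and 4 fell. Their list had already been seen to rise at 14 of 23 members, which fixed a median above 0 for these 19 beforehand. The 19 targets can therefore neither exclude nor support such a response. Of the glycolysis members outside the hypoxia list, 15 of 17 rose and 1 fell. That list is a selection of targets, so these 17 may still include hypoxia targets and do not speak against such a response. Whether the oxygen or density of the cultures differed is not recorded, and an effect of the knockdown is open.

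The ribosomal protein list rose at 74 of 75 members, with a median of 0.43 and a middle range of members from 0.34 to 0.52. Genes of other function were matched on count and on the length of the longest annotated transcript, 225 in all. Their median was 0.06, which argues against abundance as the cause. That length had a median of 1857 bases for the list and need not be that of the transcripts counted. The match therefore cannot decide on a bias towards short transcripts. Counts of ribosomal protein pseudogenes in shCON came to 31.9% of the counts that the list gained, and their own median log2 fold change was 0.33, so that reads moving from pseudogenes cannot account for the rise. Scaling left the median at 0.30 or above in each alternative, the lowest with quantile scaling of FPKM. The rise may follow from the knockdown, a hypothesis untested beyond the comparison that showed the rise.

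Targets of the aryl hydrocarbon receptor (AHR) were noticed among the falls: CYP1A1 fell from 2.24 ± 0.17 to 0.147 ± 0.031 FPKM, CYP1B1 from 104 ± 3.1 to 29.3 ± 0.85 FPKM and TIPARP from 46.6 ± 1.6 to 6.37 ± 0.25 FPKM (SD, n = 3). The hypothesis of lower AHR activity was tested on 8 other targets whose own values had not been seen, although 3 belong to lists whose totals had been. Their median log2 fold change was -0.30, 5 fell and 1, ALDH3A1, rose. That rise, of 4.89 on the log2 scale, was the largest change of the 8. It went from 0.0127 ± 0.022 to 0.398 ± 0.071 FPKM, a level near 0. The 5 targets outside the lists had a median of -0.32, and their set test did not reach 0.05. The set test of all 8 alone was under 0.05, the bound set beforehand, but over both lists tested in this way it was not (camera adjusted p = 0.057). The values are consistent with the hypothesis only without that adjustment, and the largest fall among them, SERPINB2 at -2.70, also answers to inflammatory signals.

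PMEPA1 and SMAD7, feedback genes of TGF-beta, fell: PMEPA1 was at 197 ± 9.3 and 26.6 ± 0.81 FPKM and SMAD7 at 18.0 ± 0.59 and 6.24 ± 0.68 FPKM in shCON and shPGAM5. SMAD6, with a log2 fold change of 0.17, did not pass (edgeR adjusted p = 0.20). The hypothesis of lower SMAD-dependent transcription was tested on 16 targets whose own values had not been seen, 4 of which belong to lists whose totals had been. Their median was -0.33, but 8 fell and 6 rose and the set test did not pass (camera adjusted p = 0.59), so that the hypothesis stays open. The 12 targets outside the lists also had a median of -0.33. Among the 6 of 16 that rose, ID1, a target of the BMP branch, went from 31.7 ± 1.7 to 93.8 ± 7.2 FPKM. The others, LTBP2, JUNB, CCN2, ID3 and ADAM19, rose by 1.12, 1.04, 0.71, 0.52 and 0.46 on the log2 scale.

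Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 8754 changed genes, and the highest of the others gave 0 with edgeR. At an unadjusted edgeR p under 0.05 the highest of the others gave 325, and limma on FPKM gave 0 adjusted. For lists past the threshold, 1 of the 10 splits, the real one, gave 12, and the others gave 3 to 9. Camera with the preset correlation thus called lists in splits where 0 genes passed, which also limits the 12 list calls of the real split. With 10 splits the share cannot be under 0.1. Each of the other splits mixed shCON and shPGAM5 libraries within its groups. The difference between shCON and shPGAM5 then counted as spread within those groups, which hinders calls. The gene counts of the other splits, the 0 included, therefore give no rate of false calls for the real split. Their list counts give no such rate either, because their groups still held unequal numbers of shCON and shPGAM5 libraries.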
